A study of Mus musculus with 8 samples.

How the data were processed

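Gene expression was measured in 8 samples of mouse embryonic fibroblasts (MEFs) that lacked the endogenous gene for STING, the endoplasmic reticulum adaptor that relays the cGAS signal for cytosolic DNA to the kinase TBK1 and the transcription factor IRF3. Per the labels, the cells carried the empty retroviral vector pBabe, human STING (hSTING), the mutant N154S, which the series' design text assigns to the autoinflammatory disease SAVI, or the variant R284S. Each of the 4 constructs had 1 control sample and 1 sample treated with double-stranded DNA (dsDNA) in Lipofectamine 2000 for 9 h. There were no replicates of a construct and treatment, so no mean and SD per group is given. The labels do not say whether the control cells received the transfection reagent without DNA.

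Per the labels' protocols, total RNA was extracted with a column kit and 300 ng per sample was prepared with the GeneChip WT PLUS reagents for Affymetrix arrays. Per the submitters' processing notes, Affymetrix Expression Console 1.3.1.187 was used. The algorithm, background correction and summarisation are not given in the sources used here. The deposited values are on the log2 scale, rounded to 2 decimals, and hold 41345 probe sets per array. Array medians lay between 3.79 and 3.85, and the sorted values of any 2 arrays differed by at most 0.25, so the deposited log2 values had been brought to nearly the same distribution before they were deposited. A log2 array signal has no true zero and compresses large changes, and no detection call was used here, so a low signal is not read as absence. For arrays, their number limits the precision.

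Probe sets were named through the platform annotation supplied with the values. Of the probe sets, 23521 had 1 gene symbol, 1814 had several and 16010 were not listed there. Only those with 1 symbol entered the comparisons, and the Entrez identifiers of 23328 of them were found in the RefSeq gene table of assembly GRCm38.p6, with 0 differing symbols. The array's own build is not given in the sources used here, so no coordinates are printed. For the 1082 genes with several probe sets, the probe set with the highest mean over the 8 arrays was used, which left 22180 genes, 18964 of them protein coding. Symbols whose probes can cross-react with near-identical copies, among them the interferon alpha genes, the Ifi200 family (Ifi204, Ifi205, Ifi209), Ifit3 and Ifit3b, are uncertain. Some list members were not analysed here.

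The designs, the 18 gene lists and the rule for named genes were fixed before the data were examined. For each of 10 comparisons of 2 arrays, the log2 difference was computed without a test. A fold was given as a lower bound where the dimmer signal lay below the median of the named genes of its array, with that median in its place, and bounds of fitted construct differences were computed likewise, both choices made after the data were seen. Genes differing 2-fold or more, list members included, were counted if the brighter array was at or above its median over named genes. The 10 highest and 5 lowest of these genes were eligible to be named, together with a fixed panel of pathway and reference genes and the members of the lists. The median difference of each list was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these 2 arrays. Where a comparison of 2 arrays is given, its difference has no replicate check.

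Construct effects over both treatments, with 2 arrays per construct, and the dsDNA effect over the 4 constructs were fitted with limma 3.58.1 in R 4.3.3, with construct and treatment as additive terms, moderated by eBayes, and with Benjamini-Hochberg adjustment over all genes at 0.05. The fit had 3 residual degrees of freedom and 4.03 prior degrees of freedom. Its residual holds the unevenness of the dsDNA effect between constructs together with noise, so its p-values set an average difference against that unevenness and not against replicate cultures. Each construct was a single cell population, so a construct effect includes any other difference between the populations. A second fit set the dsDNA effect in the 3 STING lines against that in the vector line, with 2 residual degrees of freedom. Up to 10 genes per direction and coefficient that passed the threshold were eligible to be named. The lists were tested with camera at its preset correlation of 0.01 over the 144 pairs of list and coefficient, and again with an estimated correlation. The second test rests on the 3 or 2 residual degrees of freedom, and its residual holds dsDNA unevenness that list members share. A list that did not pass it is therefore not read as unshifted.

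The fit was tested on simulated data built from the fitted means and residual SDs of the 22180 genes. For a simulated difference of R284S from hSTING, 35 of 100 genes changed by 1 and 91 of 100 changed by 2 on the log2 scale were recovered, with 4 false calls. For a simulated dsDNA effect across constructs these numbers were 63 and 98, with 3 false calls. The simulated noise was independent between genes and arrays, without the uneven dsDNA effect that genes share in the real residual. These numbers therefore describe that simpler setting and not the error of the fit on the real arrays. Of 100 lists of 20 unchanged genes, 4 fell outside the central 95 percent of random lists, as did 20 of 20 lists shifted by 0.5, both on the comparison of dsDNA with control in R284S cells. The unchanged lists were themselves drawn at random, so a share near this was fixed in advance. Neither number covers lists whose members vary together. Alternatives were quantile normalization, centring each array on its median, a filter on dim genes or its absence, eBayes with a trend and robust variances, the mean of a gene's probe sets, leaving out the pair of arrays of a construct, the estimated correlation, and lists restricted to brighter members. Counts over protein coding genes alone, counts with dim signals raised to the median and a list of NRF2 target genes were added after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.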

Results

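Expression was measured on 8 arrays, from STING-deficient MEFs carrying the empty vector, hSTING, N154S or R284S, each as a control culture and after dsDNA for 9 h. There was 1 array per construct and treatment and hence no replicates. Values are log2 array signals as deposited, and differences are on the log2 scale. A fold whose dimmer signal lay below the median of the named genes of its array is given as a lower bound, against that median. Fitted differences with such a signal are given as, or followed by, the bound computed in the same way. Those of Zbp1 against vector cells are given without it, since its vector control signal of 4.44 lay just under the median of 4.45. The endogenous gene Sting1 read between 3.68 and 4.22 on all 8 arrays, below the median of the named genes, which was 4.42 to 4.47. The part of Sting1 that was deleted is not given in the sources used here and the human sequence was not read out separately, so this probe set does not check the labels. Pearson's r between 2 arrays across probe sets lay between 0.973 and 0.989, and probe sets are not independent replicates.

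The comparison of control cells asked how gene expression in each STING line differed from that in vector cells without added DNA. Cells with hSTING had higher signals than vector cells for genes of the antiviral interferon program. The deubiquitinating enzyme of Isg15, Usp18, was 65.8-fold higher at 10.88 against 4.84. Ifit1, which binds viral RNA, was at least 35.0-fold higher, the ubiquitin-like modifier Isg15 23.75-fold and the transcription factor Irf7 21.86-fold. Rtp4, Oasl2, Ifi205, Ifi204, the interferon-induced GTPase Gbp3 and the nucleic acid sensor Zbp1 were each at least 5.70-fold higher. Of the 49 measured interferon-stimulated genes, 40 were 2-fold or more higher and 0 were lower, with a median difference of 2.33 at percentile 100 of the random lists. The class I antigen presentation list, with 9 of 16 members 2-fold or more higher, had a median of 1.13. The chemokine Ccl5 differed by 3.86, from 4.74 to 8.60, while Ifnb1, which encodes interferon beta, read 3.21 and 3.18. In all, 92 genes were 2-fold or more higher and 4 were lower, the latter being Sprr2k, 2.144-fold lower, and Ulbp1, Mcpt1 and Snord88a, at least 2.16-fold, 1.49-fold and 1.27-fold lower.

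Over both treatments, 22 genes rose in hSTING cells against vector cells in the limma fit and 0 fell, with 2058 genes at an unadjusted p under 0.05. Zbp1 was higher by 4.25 (SE 0.27, adjusted p = 0.015) and the apoptosis factor Xaf1 by 3.08 (SE 0.23, adjusted p = 0.015). Irf7, Oasl2, Ifi204, Gbp3, the nuclear body protein Sp100, Trim30d, Parp12 and Rnf213 also passed, each higher by at least 2.17. Of the interferon-stimulated list, 12 members rose over all genes and 48 adjusted over the list alone. The camera test of that list gave an adjusted p of 4.89e-71, and adjusted p = 0.562 with an estimated correlation. Psmb8, an immunoproteasome subunit, was the class I antigen presentation gene that rose, while 15 of 16 rose adjusted over the list alone. The count of 22 became 0 without the N154S pair of arrays and 47 without the R284S pair. With eBayes with a trend and robust variances 31 genes passed, with 13 of the 22 among them, and of the first 10 genes named here Zbp1, Xaf1 and Rnf213 passed while 7 did not.

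**Figure D1:**
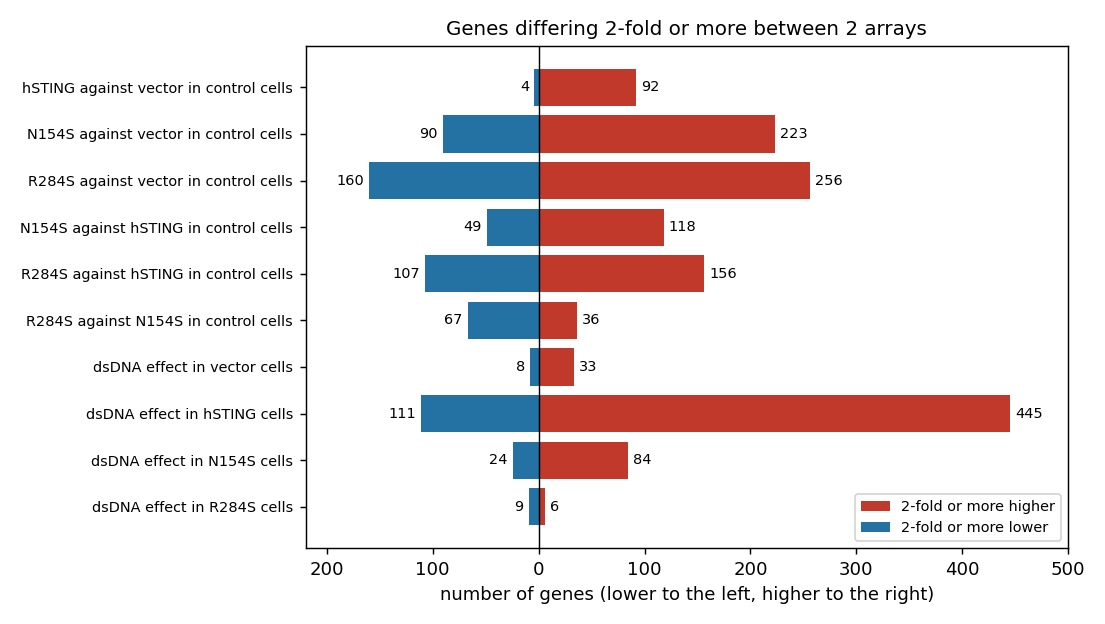
Number of genes (x axis) that differed 2-fold or more between 2 arrays, for each of the 10 comparisons (y axis), with lower genes to the left and higher genes to the right. The bar for dsDNA in hSTING cells reaches 445 higher and 111 lower genes, and the bar for dsDNA in R284S cells 6 and 9.

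Control cells with N154S had 223 genes 2-fold or more higher and 90 lower than vector cells. Ccl5, which attracts T cells, was 178.5-fold higher at 12.22 against 4.74, and the chemokine Cxcl10 73.52-fold higher. Ifit1 was at least 101-fold and Usp18 111.4-fold higher, and the mitochondrial nucleotide kinase Cmpk2, the GTPase Iigp1, Oasl2, Irf7, Rtp4 and Gbp3 were each at least 16.4-fold higher. Of the 49 interferon-stimulated genes, 47 were 2-fold or more higher, with a median of 3.65 at percentile 100. At the other end were the small proline-rich gene Sprr2k (6.681-fold lower), the protease inhibitor Serpina3n (4.659-fold), the Y RNA Rny3, the granzyme Gzmd and the glycosyltransferase Galnt16. Ifnb1 read 2.82, against 3.18 in vector cells.

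In the fit over both treatments, 157 genes rose and 135 fell in N154S against vector cells. Among the interferon-stimulated genes 41 rose over all genes and 48 adjusted over the list alone. Ccl5 was higher by 7.69 (SE 0.90, adjusted p = 0.0141) and Iigp1 by 5.71 (SE 0.64, adjusted p = 0.0124), with a bound of 5.05. In the class I list, 8 of 16 genes rose, among them H2-Q4 by at least 3.86, H2-K1 by 3.59, Psmb8 by 2.94 and the peptide transporter Tap1 by 2.56, and 15 rose adjusted over the list alone. The genes that fell included Sprr2k at -2.70 (SE 0.16, adjusted p = 0.00338, bound -2.48), Serpina3n with a bound of -2.46, the neuronal tubulin Tubb3 at -2.20, the collagen Col6a3 at -1.80 and the smooth muscle actin Actg2 at -1.79. For the interferon-stimulated and class I lists camera gave adjusted p values of 2.11e-59 and 7.61e-19, and for both adjusted p = 0.562 with an estimated correlation. The count of 292 became 178 without the R284S pair of arrays and 594 without the hSTING pair. It became 290 higher and 372 lower genes with the filter on dim genes, and 291 and 435 with eBayes with a trend and robust variances.

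Control cells with R284S had 256 genes 2-fold or more higher and 160 lower than vector cells. Ccl5 was 308.7-fold higher, at 13.01 against 4.74, Ifit1 at least 133-fold, Cxcl10 135.3-fold and Cmpk2 at least 61.0-fold higher. Oasl1, Usp18, Rtp4, Oasl2, the RNA sensor Ifih1 and Acod1, the enzyme that makes itaconate, were each at least 32.4-fold higher. Of the interferon-stimulated genes 41 of 49 were 2-fold or more higher, with a median of 2.94, and of the 8 interferon-induced chemokines 7 were. Among the lowest genes, those for the secreted matrix proteins Egfl6, Abi3bp and Dpt stood beside Gzmd and Sprr2k. Egfl6 was 18.64-fold lower at 4.89 against 9.11, Gzmd at least 4.63-fold, Abi3bp at least 4.20-fold, Sprr2k 6.727-fold and Dpt 6.233-fold lower. Ifnb1 read 4.06, and the NF-kB feedback inhibitor Tnfaip3 read 8.24 against 5.54. The NF-kB and inflammatory list as a whole differed less, with a median of 0.50, and 3 of 34 members were 2-fold or more higher and 0 lower.

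In the fit, 226 genes rose and 227 fell in R284S against vector cells. Of the interferon-stimulated genes 33 rose over all genes and 42 adjusted over the list alone, and of the class I genes 4 and 9. Ccl5 was higher by 8.23 (SE 0.90, adjusted p = 0.00921), Serpinb9e by at least 3.21, Sprr1a by 4.73, Ifih1 by 4.71 and Zbp1 by 4.37. Egfl6 was at -4.51 (SE 0.20, adjusted p = 0.00165, bound -4.46), Gzmd and Abi3bp had bounds of -2.13 and -2.10, Dpt was at -2.76, the proteoglycan Aspn at -2.31 and the Wnt antagonist Sfrp1 at -2.27. The camera tests of the interferon-stimulated and class I lists gave adjusted p values of 3.18e-40 and 4.08e-11, and for both adjusted p = 0.562 with an estimated correlation. The count of 453 became 129 without the N154S pair of arrays. It became 761 with the filter on dim genes and 854 with eBayes with a trend and robust variances.

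Part of the genes of the fibroblast matrix and of the cell cycle were lower in both mutant lines than in vector cells, in list tests that did not pass with an estimated correlation. Of the 25 measured matrix genes, 6 fell in N154S cells over all genes and 15 adjusted over the list alone, and in R284S cells 9 and 17. The largest of these in R284S cells were Col3a1 at -2.27 (SE 0.14, adjusted p = 0.00187), Col6a2 at -2.10, Col6a1 at -1.90 and Col1a1 at -1.27. In N154S cells the same 4 genes were at -1.41, -1.61, -1.48 and -0.84. In hSTING cells 0 matrix genes fell over all genes and 3 adjusted over the list alone, and the list had a median of -0.19 with a camera adjusted p of 2.50e-06, and adjusted p = 0.562 with an estimated correlation. Of the 31 cell cycle genes, the mitotic cyclin Ccnb2 and the centromere histone Cenpa fell in N154S cells, and Ccnb2, Cenpa, Plk1, Ccna2 and Tpx2 fell in R284S cells, at -1.09 to -0.72. Adjusted over the list alone, 16 fell and 2 rose in N154S cells and 20 fell in R284S cells. For R284S against vector, camera gave adjusted p values of 2.33e-16 for the matrix and 2.17e-13 for the cell cycle list, and for N154S 9.99e-13 and 2.75e-05. With an estimated correlation, adjusted p = 0.562 for the matrix list in both lines and for the cell cycle list in R284S cells, and adjusted p = 0.567 for the cell cycle list in N154S cells.

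Other lists were also compared with vector cells in the fit, and none passed with an estimated correlation. In R284S cells the lysosomal and autophagy list had a median of 0.21 (camera adjusted p = 0.00124), with the lysosomal glycoprotein gene Gpnmb rising by 0.88 and 3 of 19 members rising adjusted over the list alone. For this list adjusted p = 0.562 with an estimated correlation. The immediate early list had medians of -0.17 in N154S and -0.24 in R284S cells, where Egr2 fell in both and Nr4a1 in R284S cells, and adjusted over the list alone 2 and 3 of 16 fell. Its camera adjusted p values of 0.0422 and 0.00111 went to adjusted p = 0.579 and adjusted p = 0.562 with an estimated correlation. In the unfolded protein response list Herpud1 fell and the stress transcription factor Ddit3 rose in N154S cells, and the asparagine synthetase Asns fell in R284S cells, with 3 and 4 of 21 falling adjusted over the list alone and 1 rising in N154S cells. Its camera adjusted p values were 0.0103 and 0.0425, and adjusted p = 0.579 and adjusted p = 0.66 with an estimated correlation. Of the p53 targets, Perp rose by 0.98 in R284S cells, and the list had camera adjusted p values of 0.363 in R284S and 0.244 in N154S cells. The type I interferon list had medians of 0.02 and -0.02, with 0 of 15 members passing either way. Its median signal lay between 3.04 and 4.10 on the 8 arrays, below the median of the named genes, so a change may have gone unseen. Of the pathway's own components, the RNA editing enzyme Adar rose by 1.75 in N154S and 1.07 in R284S cells. For the kinase Tbk1 the control signals were 7.46, 7.44, 7.89 and 7.92 in vector, hSTING, N154S and R284S cells, for Irf3 6.02, 6.15, 5.81 and 5.96, and for Cgas 4.91, 5.14, 5.56 and 4.64.

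The mutant lines were next set against the hSTING line. Each line was a single cell population and the human sequence was not read out separately, so differences cannot be assigned to the amino acid changes alone. In control cells N154S had 118 genes 2-fold or more higher and 49 lower than hSTING. Ifi209 was at least 12.9-fold, Acod1 at least 6.63-fold and Ccl5 12.3-fold higher, followed by Cxcl11, Oasl1, the antiviral protein Rsad2, Serpinb9e, the ubiquitin ligase Neurl3, Cmpk2 and the pore-forming protein Mpeg1. The lowest were the small RNAs n-R5s136, Rny3 and Rny1, the linker histone H1f5 and Sprr2k, at -1.97 to -1.51. Of the interferon-stimulated genes 24 of 49 were 2-fold or more higher in N154S, with a median of 1.12 at percentile 100. Over both treatments 0 genes passed in the limma fit, where 1974 had an unadjusted p under 0.05 and the smallest adjusted p was 0.0709. This fit averages the 2 treatments, and with dsDNA some of these genes read alike in both lines. Ccl5 then read 12.70 in hSTING and 12.79 in N154S cells, and Acod1 10.76 and 10.42. The 0 is thus no sign that the control cells were alike. The interferon-stimulated list had a median of 0.50 over both treatments with 0 members passing either way, a camera adjusted p of 1.55e-06, and adjusted p = 0.686 with an estimated correlation. With eBayes with a trend and robust variances, 125 genes passed.

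R284S control cells had 156 genes 2-fold or more higher and 107 lower than hSTING control cells. Acod1 was at least 36.8-fold higher, Cxcl11 at least 23.3-fold, Neurl3 23.75-fold, Ccl5 21.26-fold and the cornified envelope gene Sprr1a 18.9-fold. The lowest were the lipocalin Apod, at least 7.89-fold lower, then Egfl6, Gzmd, Dpt and Abi3bp. Of the interferon-stimulated genes 8 were 2-fold or more higher, with a median of 0.23, and the chemokine list had a median of 1.72 with 5 of 8 members 2-fold or more higher. Over both treatments the chemokine list did not pass, with a median of 0.232, 0 members passing either way and a camera adjusted p of 0.89. In the fit over both treatments 113 genes rose and 98 fell. The metalloreductase gene Steap4 was higher by 2.63 (SE 0.13, adjusted p = 0.00234), the aldo-keto reductase Akr1c18 by 2.12, Il13ra2 by at least 0.94 and the class II gene H2-Ab1 by 1.81. Apod was at -4.32 (SE 0.45, adjusted p = 0.0138, bound -3.82), the amino acid transporter Slc7a5 at -1.97, the heparan sulfate proteoglycan Gpc3 at -1.90 and the complement inhibitor Serping1 at -1.85. Of the 25 matrix genes 5 fell over all genes and 13 adjusted over the list alone, with a camera adjusted p of 1.41e-10, and adjusted p = 0.562 with an estimated correlation. In the interferon-stimulated list 0 members passed either way, and its median over both treatments was -0.42, opposite in sign to that in control cells (camera adjusted p = 1.24e-05, and adjusted p = 0.695 with an estimated correlation). The count of 211 became 79 without the vector pair of arrays and 47 without the N154S pair. It became 252 higher and 203 lower genes with the filter on dim genes, and 322 and 262 with eBayes with a trend and robust variances.

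Between the mutants, R284S control cells had lower signals than N154S control cells for part of the interferon-stimulated genes, and higher ones for some chemokines and lower ones for others. R284S had 36 genes 2-fold or more higher and 67 lower. Acod1 was 5.54-fold higher in R284S, Steap4 4.141-fold, the chemokine Ccl3 at least 2.79-fold and Sprr1a 3.811-fold, and Capn6, Neurl3, Ifi27, Cxcl11 and the peptidase Mme were 3.031-fold to 3.681-fold higher. For Ifi27 the gap came from a low N154S signal, since it read 7.97 in R284S, 6.23 in N154S and 7.84 in vector control cells. Apod was at least 22.8-fold lower, Ifi209 at least 12.8-fold, Egfl6 5.426-fold, Phf11b 5.352-fold and Mpeg1 at least 1.97-fold lower. Of the 49 interferon-stimulated genes 12 were 2-fold or more lower and 1 higher, with a median of -0.64 at percentile 0. The class I list had a median of -0.59, with 5 of 16 lower, while the chemokine list had a median of 0.84, with Cxcl9 at -1.99 and Ccl8 at -0.49. Over both treatments the chemokine list did not pass (median 0.31, mean -0.04, adjusted p = 0.89). Irf7 read 9.66 in R284S and 11.02 in N154S cells, and Tnfaip3 8.24 and 6.99. In the limma fit over both treatments Steap4 rose by 2.14 (SE 0.13, adjusted p = 0.0171) and Egfl6 fell, at -2.75 (SE 0.20, adjusted p = 0.0263, bound -2.70). These were the 2 genes that passed, and the count became 0 without the vector pair of arrays and 7 without the hSTING pair. For the interferon-stimulated list 0 genes passed over all genes and 21 of 49 fell adjusted over the list alone, and camera gave an adjusted p of 3.22e-22 and adjusted p = 0.562 with an estimated correlation.

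**Figure D2:**
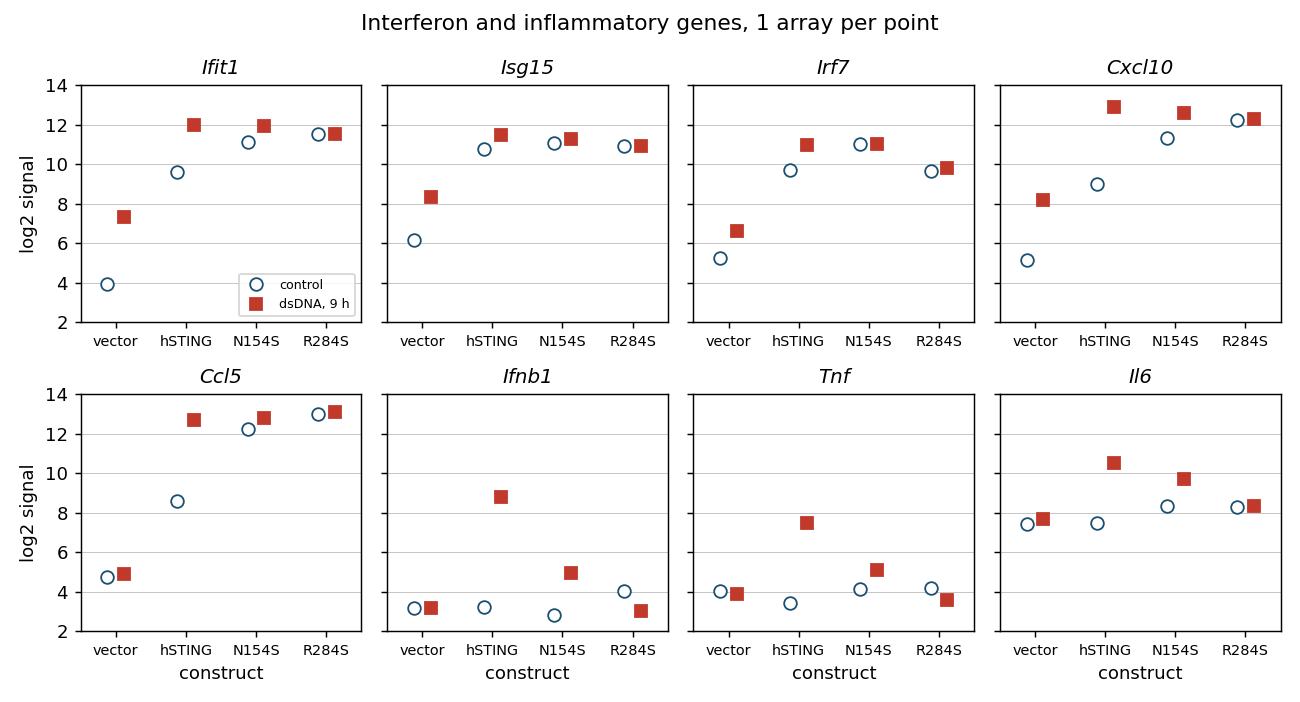
Log2 signal (y axis) of 8 genes of the fixed panel in the vector, hSTING, N154S and R284S lines (x axis), as open circles for control and filled squares for dsDNA, each from 1 array. Ccl5 reads 4.74 and 4.89 in the vector line and 13.01 and 13.09 in the R284S line, and Ifnb1 goes from 3.21 to 8.80 in the hSTING line.

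Treatment with dsDNA was then compared with control within each line. The vector line lacked STING, and there 33 genes were 2-fold or more higher with dsDNA and 8 lower. Ifit1 was at least 7.46-fold higher, at 7.35 against 3.94, Usp18 8.815-fold and Cxcl10 8.456-fold higher. Rtp4, Cmpk2, Isg15, Oasl2, Gm20559 and Ifi205 were each at least 2.14-fold higher, and Iigp1 at least 1.40-fold. Of the 49 interferon-stimulated genes 16 were 2-fold or more higher and 0 lower, with a median of 0.81 at percentile 100. Ifnb1 read 3.18 on both arrays, Ccl5 4.74 and 4.89, and 0 of 34 NF-kB and inflammatory genes were 2-fold higher or lower. Among the lower genes, the small RNAs Mir3473c and Snora44 and Olfr1269 were 2.25-fold to 2.395-fold lower, Mir5123 at least 1.48-fold and Gm6909 at least 1.02-fold. Without the filter on dim genes the total of 41 became 91.

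In hSTING cells 445 genes were 2-fold or more higher with dsDNA and 111 lower. Acod1 was at least 79.3-fold higher, at 10.76 against 3.24, Cxcl11 at least 43.4-fold, Ifit1bl1 at least 11.2-fold and Ifnb1 at least 20.4-fold higher. Gm12250, the chemokine Ccl12, the chemokine receptor Ccrl2, the alarmin Il33, Ifi209 and Neurl3 were each at least 7.26-fold higher. All 8 interferon-induced chemokines, 39 of 49 interferon-stimulated genes, 19 of 34 NF-kB and inflammatory genes, 12 of 16 class I genes and 5 of 15 type I interferon genes were 2-fold or more higher, with medians of 3.99, 1.84, 1.19, 1.36 and 0.41. Tnf went from 3.44 to 7.50, Il6 from 7.48 to 10.50 and Cxcl1 from 6.85 to 8.91. Within the cell death list, 7 of 19 members were 2-fold or more higher, among them the necroptosis effector Mlkl, at 10.34 against 8.35, and the caspase Casp4, at 9.10 against 7.02. Among the lower genes, the mesenchymal transcription factor Osr1, Trav9d-3, Kif26b and the Wnt regulator Dact1 were 3.458-fold to 3.706-fold lower and Setbp1 at least 2.79-fold.

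In N154S cells 84 genes were 2-fold or more higher with dsDNA and 24 lower. Acod1 was 9.448-fold higher, Ccrl2 at least 5.24-fold, the GTPase Gbp5 6.105-fold, Cxcl11 5.979-fold and the cytokine Tslp 5.464-fold higher. The cystine transporter Slc7a11, Il33 and Cmpk2 were 4.659-fold to 4.823-fold higher, the chemokine Ccl4 at least 2.38-fold and Trim30c at least 1.66-fold. Ifnb1 read 4.95 against 2.82 and Il6 9.71 against 8.36. Of the interferon-stimulated genes 10 of 49 were 2-fold or more higher, with a median of 0.52, from a control level of 8.55 for the list median. Of the NF-kB and inflammatory genes 8 of 34 were, with a median of 0.46. Among the lower genes, Snora44, the smooth muscle gene Lmod1 and the protocadherin Pcdh18 were 2.732-fold to 3.227-fold lower, and Mir145a and Mir300 at least 1.01-fold.

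In R284S cells 6 genes were 2-fold or more higher with dsDNA and 9 lower. Slc7a11 was 5.278-fold higher, at 7.39 against 4.99, and Prl8a9 2.071-fold, while Selenbp1, Fbxo16, D530049I02Rik and Sprr2h were at least 1.97-fold, 1.91-fold, 1.16-fold and 1.10-fold higher. The quinone reductase Nqo1 was 1.972-fold higher. Of the interferon-stimulated, chemokine, class I and NF-kB lists 0 members were 2-fold or more higher. Their medians were 0.08, 0.10, 0.04 and 0.02, and the first was at percentile 99.95 of the random lists. Ifnb1 read 3.04 with dsDNA and 4.06 in the control, Il6 8.34 and 8.29, and Tnf 3.61 and 4.18. Among the lower genes, Snora44, Tuba1b, Snord69 and Snora15 were 2.428-fold to 3.811-fold lower and 4933416I08Rik at least 1.01-fold. Without the filter on dim genes the total of 15 became 59, over protein coding genes alone 9, and with dim signals raised to the median also 9.

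**Figure D3:**
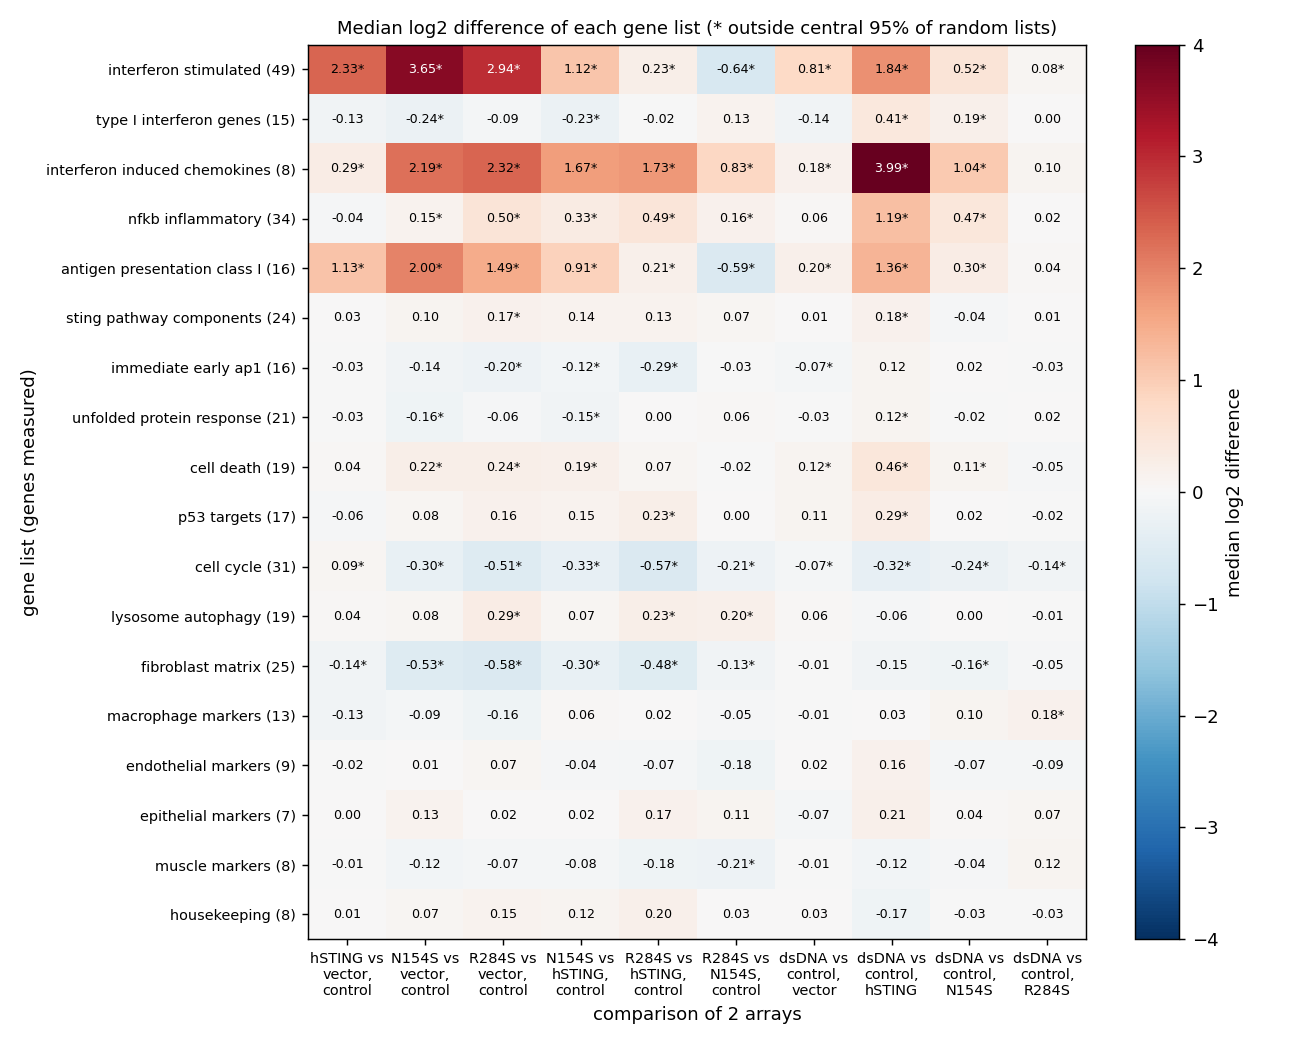
Median log2 difference of each of the 18 gene lists (y axis, with the number of genes measured) in each of the 10 comparisons of 2 arrays (x axis), with colour from -4 to 4 and a star where the median lies outside the central 95 percent of matched random lists. The interferon-stimulated list is at 1.84 for dsDNA in hSTING cells and at 0.08 in R284S cells.

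Across the 4 constructs 0 genes passed for the dsDNA effect in the limma fit, with 2395 genes at an unadjusted p under 0.05. The smallest adjusted p, 0.0586, belonged to Slc7a11, higher by 2.08 (SE 0.15) and higher in 4 of 4 lines. Of the interferon-stimulated genes 28 of 49 rose adjusted over the list alone, with a median of 0.80 and a camera adjusted p of 1.40e-23, and adjusted p = 0.562 with an estimated correlation. For the NF-kB list camera gave an adjusted p of 5.22e-10 with 0 members passing either way, and adjusted p = 0.607 with an estimated correlation. The cell cycle list had a median of -0.23 with 0 members passing either way, a camera adjusted p of 6.86e-09, and adjusted p = 0.562 with an estimated correlation. Actb was between 10.19 and 10.59 and Gapdh between 12.48 and 12.72 on all 8 arrays.

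The difference of the dsDNA effect between the 3 STING lines and the vector line was tested directly. For this difference 0 genes passed in the limma fit, 798 had an unadjusted p under 0.05 and the smallest adjusted p was 0.994. For the NF-kB and inflammatory list this difference had a median of 0.53 with 0 members passing either way, a camera adjusted p of 1.20e-05, and adjusted p = 0.695 with an estimated correlation. It came from the hSTING and N154S lines, since the dsDNA median of the list was 0.02 in R284S and 0.06 in vector cells. The class I list, at 0.33, had adjusted p = 0.0342, and adjusted p = 0.732 with an estimated correlation, and its dsDNA medians were 1.36 in hSTING, 0.30 in N154S, 0.04 in R284S and 0.20 in vector cells. The interferon-stimulated list, at 0.04, did not pass (adjusted p = 0.199), with 0 members passing over all genes and 3 lower adjusted over the list alone. Its dsDNA medians were 1.84 in hSTING, 0.52 in N154S, 0.08 in R284S and 0.81 in vector cells. They started from control list medians of 6.98, 8.55, 7.86 and 4.44 in the same order. The 0.04 thus averages unlike values and is no sign that the lines responded alike. Across the 22180 genes, the dsDNA differences of the hSTING and N154S lines, which share no arrays, correlated with Pearson's r of 0.441 and Spearman's rho of 0.322. The other 5 pairs of lines had r between 0.087 and 0.124 and rho between 0.089 and 0.146. These are correlations across genes, which are not independent replicates.

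Markers of other cell types were read as lists. The list medians over the 8 arrays lay between 3.64 and 4.33 for macrophage, 3.68 and 4.07 for endothelial, 4.04 and 4.65 for epithelial and 4.26 and 4.69 for muscle markers. Against vector cells, the tight junction gene Cldn4 rose by at least 1.03 in R284S cells, Flt1, a receptor for vascular growth factors, fell in N154S cells at -0.94 and in R284S cells at -1.81, and the intermediate filament gene Des fell in R284S cells at -1.04. Camera called the epithelial list in R284S against vector (median 0.16, adjusted p = 0.0325), and adjusted p = 0.562 with an estimated correlation. The macrophage markers had a median of 0.18 for dsDNA in R284S cells, at percentile 98.6, with 0 of 13 members 2-fold or more higher. The housekeeping list had medians between -0.17 and 0.20 in the 10 comparisons of 2 arrays.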

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

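The lists and fits here were planned, while the comparison of single genes between lines and the count over unnamed probe sets were chosen after the results were seen. No group held several arrays, so no test for an array that stands apart from its group was possible.

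For 3 gene lists the dsDNA effect differed between the STING lines and the vector line in the camera test of the difference itself. The NF-kB and inflammatory list had a median log2 difference of 0.525 (adjusted p = 1.20e-05), the class I antigen presentation list 0.325 (adjusted p = 0.0342) and the cell cycle list -0.197 (adjusted p = 0.0026). With an estimated correlation these were adjusted p = 0.695, adjusted p = 0.732 and adjusted p = 0.66. The dsDNA effect in the 3 STING lines is an average of unlike values. In hSTING, N154S and R284S cells the single-line medians were 1.19, 0.46 and 0.02 for the NF-kB list, against 0.06 in vector cells. For the class I list they were 1.36, 0.30 and 0.04, against 0.20 in vector cells, so the R284S median was near 0 and below that of vector cells. For the cell cycle list they were -0.32, -0.24 and -0.14, against -0.07 in vector cells.

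For 2 noncoding or uncharacterised genes the signal's dsDNA difference had opposite signs in different lines, each on 1 array per side, and the difference was not tested. The small nucleolar RNA Snora44 was higher by 1.38 in hSTING cells and at -1.93 in R284S, -1.69 in N154S and -1.18 in vector cells. The gene 4933416I08Rik went from 2.95 to 4.55 in vector cells, a difference of 1.60, and from 4.48 to 3.12 in R284S cells, a difference of -1.36. These signals lie near or under the median of the named genes, so the size of its changes is not known.

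Signals outside the named genes also differed between control R284S and vector cells. Among the 1814 probe sets with several gene symbols, 35 were 2-fold or more higher and 7 lower in R284S cells. Among the 16010 probe sets that the annotation did not list, 155 were 2-fold or more higher and 253 lower. What these probe sets measure was not analysed here.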

How the results depend on the processing

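Counts over protein coding genes alone and with dim signals raised to the median were added after the data were seen, and all other alternatives were planned. With centring on array medians, 35 genes passed for hSTING against vector and 1 for the dsDNA effect across constructs. With the filter on dim genes, which leaves fewer genes tested, 662 passed for N154S and 761 for R284S against vector, 16 for N154S and 455 for R284S against hSTING. With eBayes with a trend and robust variances, 4 passed for the dsDNA effect, 31 for hSTING against vector with 13 of the 22 among them, 726 for N154S and 854 for R284S against vector, 125 for N154S and 584 for R284S against hSTING and 12 for R284S against N154S, and the cause was not tested. When the pair of arrays of a construct was left out, which leaves fewer arrays, counts ranged from 0 to 1 for the dsDNA effect, 0 to 47 for hSTING, 178 to 594 for N154S and 129 to 654 for R284S against vector, 47 to 79 for R284S against hSTING and 0 to 7 for R284S against N154S. The difference of the dsDNA effect between STING lines and vector gave 0 genes in all 8 alternatives run. Of the 62 list tests past the threshold, 0 passed with an estimated correlation. For the epithelial list in R284S against vector the estimate was -0.053, under the preset 0.01, yet the camera p went from 0.0126 to 0.0827. With so few residual degrees of freedom, not passing does not speak against a shift. The preset in turn lies under the 0.656 estimated for the interferon-stimulated list in that comparison, so neither version settles it. Without the filter on dim genes, 91 genes differed 2-fold or more with dsDNA in vector and 59 in R284S cells, and over protein coding genes alone 9 in R284S cells. With dim signals raised to the median, 29 differed in vector, 9 in R284S and 496 in hSTING cells. The median of the muscle markers in R284S against N154S control cells turned to 0.045 over brighter members. For the named fitted genes, 443 values stayed past the threshold with their sign and 57 lost it, 26 of these under the trend and 23 without the N154S pair, and 0 changed sign. Of the values of named genes in comparisons of 2 arrays, 446 moved by no more than the gene's residual SD and 4 by more. This is a lenient check, since that SD holds the unevenness of the dsDNA effect and was 2.43 for Acod1. Quantile normalization and centring could also move little in arrays with nearly the same distribution. Signal over background limits the dim genes, for which no detection call was used.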

Other observations

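All tests of explanations given here, and the list of NRF2 target genes, were chosen after the results were seen.

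Some genes of the antioxidant NRF2 program were higher with dsDNA in all 4 lines, and for none of them did the fit across constructs pass. The cystine transporter Slc7a11 was higher by 1.50, 2.15, 2.27 and 2.40 in vector, hSTING, N154S and R284S cells, and the quinone reductase Nqo1 by 1.14, 0.37, 0.57 and 0.98. Named after their values were seen, the heme oxygenase Hmox1 was higher by 1.28, 1.05, 0.77 and 0.79, and the glutathione synthesis genes Gclm and Gclc by 1.09, 0.63, 0.50 and 0.89 and by 0.62, 0.98, 0.70 and 0.82. Of all genes, 4 were higher by 0.5 or more in every line, and they were Slc7a11, Hmox1, Gclm and Gclc. Another 4 were lower by as much in every line, namely the endothelin gene Edn1, the histone gene H2ac21, Mir5123 and the small nucleolar RNA Snord13.

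The NRF2 pattern was tested on the 16 measured list members other than Slc7a11, Nqo1, Hmox1, Gclm and Gclc. Their median was 0.355 in vector, 0.075 in hSTING, 0.085 in N154S and 0.185 in R284S cells, at percentiles 100, 92.25, 98.31 and 100 of the random lists, and 6 of 16 were higher in all 4 lines. For the dsDNA effect across constructs camera gave p = 3.60e-05, and p = 0.165 with an estimated correlation of 0.325, so a shared response to the transfection stays a hypothesis. A level shift of whole dsDNA arrays left by the normalization is argued against by the array distributions. Their sorted values differed by at most 0.25, against 0.765 or more across constructs for each of the 5 genes. The 8 housekeeping genes had a median of -0.07 (SD 0.12 across genes), which adds little, since such distributions leave no room for a larger shift of all genes. Whether DNA or the transfection reagent lies behind the pattern is open, since the labels do not say what the control cells received.

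Interferon-stimulated genes were higher with dsDNA in the vector line, which lacks STING, while Ccl5 and Ifnb1 were not. Carry-over of RNA or cells from a line with STING was weighed by computing the share needed by the 19 list genes that rose 2-fold or more, 3 of them dim on both arrays, 3.62 to 18.6 percent depending on which of the 6 other arrays was the donor. The other transcripts that this share should raise 2-fold fell short of the predicted rise by a median of at least 0.49, within the SD of 0.80 between genes for that donor, the hSTING control array. For the hSTING dsDNA array the shortfall of 0.96 lay beyond its SD of 0.84, and for the other 5 donors it lay within. The SD is the spread between genes and not the error of the median, so lying within it does not speak for carry-over. For each of the 6 donors these transcripts rose by less than predicted, by a median of up to 1.21 for the R284S dsDNA array. The share was set from list genes picked because they rose 2-fold, while list genes that rose less, such as Zbp1 and Sp100, stayed among the tested transcripts. A shortfall is thus partly built in, and the genes are not independent replicates. It therefore does not make carry-over less likely, and carry-over stays open. Ccl5 goes against it, since it read 4.89 where the 6 donors predict 6.56 to 10.2, but it is a single gene. Ifnb1 read 3.18, under the median of the array, so earlier transcription of Ifnb1 in these cells may have gone unseen, and a route that does not need STING stays open as untested.

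R284S cells showed high interferon-stimulated genes without DNA and 6 genes 2-fold or more higher with it. A ceiling of the array was tested on the 275 genes that were raised 2-fold or more by dsDNA in hSTING cells and that read 1 or more below the hSTING dsDNA level in R284S control cells. Their median was 1.75 in hSTING, 0.58 in N154S and 0.11 in R284S cells (SD 0.29 across genes), which argues against the array's range as the reason. That the R284S dsDNA array came from untreated cells stays open, since the outcome depended on the gene set and the yardstick, with 1 array per side. The set was changed several times after results were seen, and 10 versions were looked at: 4 drawn from the NRF2 list and 6 of all genes that were higher or lower by at least 0.4, 0.5 or 0.6 in the other 3 lines. In all 10 the R284S median went the way of the other lines, but it lay beyond its SD across genes in 4 of them. That SD is the spread between genes and not the error of their median. Among random lists, the 4 NRF2 versions lay at percentile 100. The version of 19 genes holds Hmox1, Gclm and Gclc, and the version of 11 genes holds these with Slc7a11 and Nqo1. These 5 genes were named after their R284S values were seen. The higher and lower genes lay at 99.94 and 0.03 for 0.4, and at 68.55 and 0.03 for 0.5. The sets of higher genes for 0.4 and 0.5 hold Gclc and Gclm, and the sets for 0.4 contain those for 0.5. By this yardstick the sets other than the one at 68.55 went against untreated cells. They overlap, and some hold genes picked from the R284S arrays, so they do not count as separate evidence. The sets for 0.6 were too small to place. In the last version, the 6 NRF2 list members other than the 5 genes named first that were higher in the other 3 lines, the median was 0.42 (SD 0.29) and all 6 read above all 4 control arrays. The 9 genes higher by at least 0.5 had a median of 0.05 (SD 0.48). No biological explanation was tested, and a lower uptake of DNA by this line stays open.

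The 8 arrays can be split into 4 and 4 in 35 ways, of which 32 could be fitted beside the construct. The real split into control and dsDNA gave 0 genes, so all 32 had to give as many and the count says nothing about chance. The highest of the other splits gave 34 genes, in 2 splits that keep the vector pair and the R284S pair of arrays each on 1 side. Beside the construct, both are the contrast of dsDNA with control in hSTING and N154S cells, with the sign turned in 1 of them. This points to a structure of the samples in which the dsDNA effect is shared by these 2 lines and uneven over the 4, though the contrast was singled out as the highest of 32. Among the 8 splits that part every construct, the highest other count was 0.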
